A study of Bos indicus x Bos taurus with 78 samples.

How the data were processed

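Small RNA was sequenced from total RNA of muscle biopsies of 78 steers, with libraries made with a NEXTflex small RNA kit, per the labels' protocols. The submitters' processing notes name FastQC, Trimmomatic 0.32 and DESeq2 1.34.0. The aligner, the counting tool, the miRNA reference and the genome build are not given in the sources used here, so no genomic positions are reported, and miRNAs are named as in the files without their species prefix. The kit adds random adapter bases, and whether repeated reads were collapsed is not given in the sources used here.

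The deposited matrix holds whole-number read counts per bovine mature miRNA and steer, without normalization, per the file headers and values. A further table deposited by the authors gives, per miRNA, the mean normalized signal of all libraries, the log2 fold change with its standard error, the Wald score, and the p-value with its adjusted p-value. The authors' deposited table names no contrast in its headers. A DESeq2 fit of dark-cutting against normal steers on the miRNAs with at least 10 counts in all libraries gave its Wald scores within 7.55e-08, which settled both the contrast and the row filter. Columns of the matrix carry the steers' title numbers, and all 78 were matched to the labels.

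Groups were taken from the phenotype label, which gives a fraction for each dark-cutting steer. Steers are separate animals by their title numbers. Replicate numbers count the steers within each group and pair none across groups, and no batch is given by the labels. The title numbers fall below 600 in 18 normal and 8 dark-cutting steers and at 600 or above in 35 and 17, which served as an added covariate. No pair of libraries was a near copy: the smallest chi-square per degree of freedom over the 3003 pairs was 9.43.

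Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with robust dispersion, TMM scaling and Benjamini-Hochberg adjustment, with a threshold of 0.05. For dark-cutting against normal the low-count filter was edgeR's filterByExpr with a minimum count of 10, which left 252 miRNAs. For the degrees and the trend, a miRNA needed the equivalent of 10 counts in at least 8 libraries and 15 counts in all, which left 272 miRNAs, or 251 within the dark-cutting steers. Each degree with at least 3 steers was compared with normal steers in one fit of all 78 libraries. The trend took normal steers as 0 and the labelled fraction as the degree. All fold changes are relative to the other miRNAs of a library, since miR-1 alone holds most counts. Log2 CPM used the TMM factors and a prior count of 2. Reads of near-identical miRNAs can be counted in more than 1 row, and 21 rows had counts identical to an earlier row.

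Lists of miRNAs for muscle, blood, vessel, fibroblast, epithelium, nerve and liver cells and for pathways were fixed before the data were examined, as were the comparisons and the rule for naming miRNAs. The rule takes, per comparison, up to 12 calls in each direction or, with fewer than 10 calls, the 10 smallest p-values, the most abundant tested members of each list, the 10 most abundant miRNAs and the calls of the authors' table. The miRNAs miR-451, miR-223, miR-150, miR-543, miR-103, miR-27a-3p, miR-378b and miR-2422, and miR-10174-3p with miR-23b-3p, miR-2284f and miR-2285cz, were chosen after their values were seen or as further examples of a list. Of these, the rule itself names miR-2422 for degrees 1/4 and 1/2 and the trend over all steers, and miR-543 for degree 1/2. Elsewhere they are outside the rule. Some miRNAs belong to more than 1 list: miR-146a, miR-146b, miR-155 and miR-223 to white blood cells and inflammation, miR-92a and miR-25 to red blood cells and the miR-17-92 list, and miR-27a and miR-27b to glucose and lipid metabolism and muscle atrophy. Both slow-fibre miRNAs are also myomiRs, miR-29b belongs to fibroblasts and atrophy, and miR-21-5p to fibroblasts and inflammation. Every listed miRNA with a value here was detected in these biopsies above the low-count filter, which does not tell from which cells it came. Lists were tested with camera and fry of limma 3.58.1 on voom values. Depth measures were compared with two-sided permutation tests of 100000 resamples.

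Each test was checked on counts simulated from the real means, dispersions and library sizes, with 48 miRNAs changed by 1.3, 1.5 or 2-fold in 10 simulations per comparison. For the trends this was the fold per 1/2 unit of degree. False calls were 2.75% of the calls in the simulated comparison of dark-cutting against normal steers, 5.56% for degree 2/3, 5.63% for higher against lower degree and 5.91% for the trend over all steers, the last 3 being above the 5% aimed at, and at most 3.96% for the others. These simulations hold no correlation between miRNAs, so they do not give the rate of false calls in the real libraries. Labels were also shuffled among the real steers, making 100 splits with the real one. Of the shuffled splits, 14 held a call for dark-cutting against normal steers and 18 for the trend over all steers. For degrees 1/4, 1/3, 1/2 and 2/3 it was 26, 29, 17 and 23, and within dark-cutting steers 6 (trend) and 4 (higher against lower). A list of 8 miRNAs shifted by 1.2-fold was called by camera in 98.0% of 50 simulations, which hold no correlation between miRNAs. Alternatives were DESeq2 1.42.0, limma-voom with sample weights, other scalings and filters, covariates including surrogate variables of sva 3.50.0, and left-out animals. Figures were drawn with matplotlib 3.10.9. Depth sets the precision of the rarer miRNAs, such as miR-1260b with 10.5 counts per normal library on average, and the median half-width of the 95% interval was 0.21 log2 units in the comparison of dark-cutting against normal steers.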

Results

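MicroRNAs were counted in Longissimus lumborum biopsies, a loin muscle, of 78 Bos indicus x Bos taurus steers. Dark-cutting beef is dark, firm and dry, and is known to follow low muscle glycogen at slaughter. The labels put 53 steers in the normal group and 25 in the dark-cutting group, with degrees of 1/4 (8 steers), 1/3 (9 steers), 1/2 (3 steers), 2/3 (4 steers) and 3/4 (1 steer). The question was which miRNAs differ with the phenotype or with its degree. Total counts per library ran from 1427817 to 4535675, with a median of 3209320. The count table held 1030 miRNA rows, of which 741 had at least 1 count and 232 had a count in every steer.

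The muscle miRNA miR-1 made up 84.1% ± 2.76 (SD, n = 78) of all counts, between 72.3% and 88.6% per steer. It was followed by miR-143, a miRNA of smooth muscle and pericytes, at 2.498% ± 0.914 (SD, n = 78), and by the muscle miRNA miR-133a at 1.91% ± 0.607 (SD, n = 78). Next came miR-22-3p at 1.07%, miR-26a at 1.04%, miR-30e-5p at 0.801%, let-7f at 0.765%, miR-499 at 0.538%, miR-126-3p at 0.483% and miR-30a-5p at 0.4656% on average. Together these 10 miRNAs held 93.7% of the counts. The share of miR-1 was 83.8% in dark-cutting and 84.2% in normal steers (permutation p = 0.545, two-sided, n = 25 and 53). Mean log10 total count was 6.52 and 6.50 (permutation p = 0.308), and the number of miRNAs with at least 1 count was 404 and 398 (permutation p = 0.259). The smallest Benjamini-Hochberg adjusted p over the 5 depth measures was 0.318.

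In the comparison of 25 dark-cutting with 53 normal steers, the miRNA with the smallest p was miR-1260b, with a log2 fold change of 0.64 ± 0.20 (SE), and 21 of the 25 dark-cutting steers lay above the normal median. The muscle-specific miR-206 had a log2 fold change of 0.16 ± 0.06 (SE), with 19 of 25 steers above the normal median. Lower values were seen for miR-144, processed from an erythroid transcript, at -0.86 ± 0.27 (SE), with 5 of 25 steers above the normal median. The same held for miR-142-5p, a miRNA of blood-forming cells, at -0.38 ± 0.13 (SE), with 6 of 25 above, and for miR-148a, at -0.23 ± 0.07 (SE), with 9 of 25 above. None of the 252 tested miRNAs passed edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment, where the smallest adjusted p was 0.182, and the count was also 0 with DESeq2 and with limma-voom. At an unadjusted p under 0.05 there were 23 miRNAs by edgeR, 7 higher and 16 lower, where 12.6 would be reached by chance, 23 by DESeq2 and 40 by limma-voom.

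The other miRNAs among the 10 with the smallest p were miR-3613a at -0.34 ± 0.12 (SE), miR-493 at 0.33 ± 0.12, miR-27a-5p at 0.46 ± 0.17, miR-136 at -0.56 ± 0.21 and miR-146a, an immune-response miRNA, at -0.42 ± 0.16. Their adjusted p lay between 0.277 and 0.295 by edgeR. One normal steer, normal replicate 19, had 8593 counts of miR-451, at 11.39 log2 CPM against at most 8.36 in any other steer, and 339 counts of miR-144. Without it the log2 fold change of miR-144 was -0.51 (95% interval -0.92 to -0.10). For miR-451, made from the same transcript, it went from -0.52 ± 0.25 (SE) with all steers to -0.06 ± 0.14 without that steer. In the 26 steers with animal numbers below 600 the log2 fold change was 0.52 ± 0.33 for miR-1260b and -0.14 ± 0.35 for miR-144. Within the 52 others, normal replicate 19 among them, these were 0.71 ± 0.24 and -1.11 ± 0.35. The log2 fold change of miR-206 was -0.01 ± 0.10 and 0.26 ± 0.07 in these ranges, and that of miR-148a was -0.03 ± 0.11 and -0.30 ± 0.09. No miRNA passed edgeR's test of a phenotype difference that differs between the ranges. An unadjusted p under 0.05 was reached by 10 of 252, miR-206 among them (p = 0.0189, adjusted p = 0.852), where chance alone would give 12.6.

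Among the 10 most abundant miRNAs none passed. The lowest p was that of miR-30e-5p, at a log2 fold change of -0.17 (95% interval -0.31 to -0.03, p = 0.0205, adjusted p = 0.416 by edgeR), with -0.32 ± 0.10 (SE) in steers numbered below 600 and -0.07 ± 0.09 in the others. The log2 fold change of miR-1 was -0.13 (95% interval -0.28 to 0.02), that of miR-133a -0.02 (-0.19 to 0.15) and that of miR-143 -0.23 (-0.47 to 0.01). Over the alternative settings that of miR-1 ran from -0.14 to -0.0070 and that of miR-30e-5p from -0.20 to -0.07. The 95% interval excluded a 2-fold difference for 249 of the 252 miRNAs and a 1.5-fold difference for 227 of them. In data simulated from these libraries with 48 changed miRNAs, the same test recovered 73.1% of changes of 1.3-fold, 93.1% of 1.5-fold and 99.4% of 2-fold. These rates are for 48 changes at once, without correlation between miRNAs. With few changed miRNAs the adjusted threshold is stricter, so the rates do not tell how often a lone change would be missed.

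**Figure D1:**
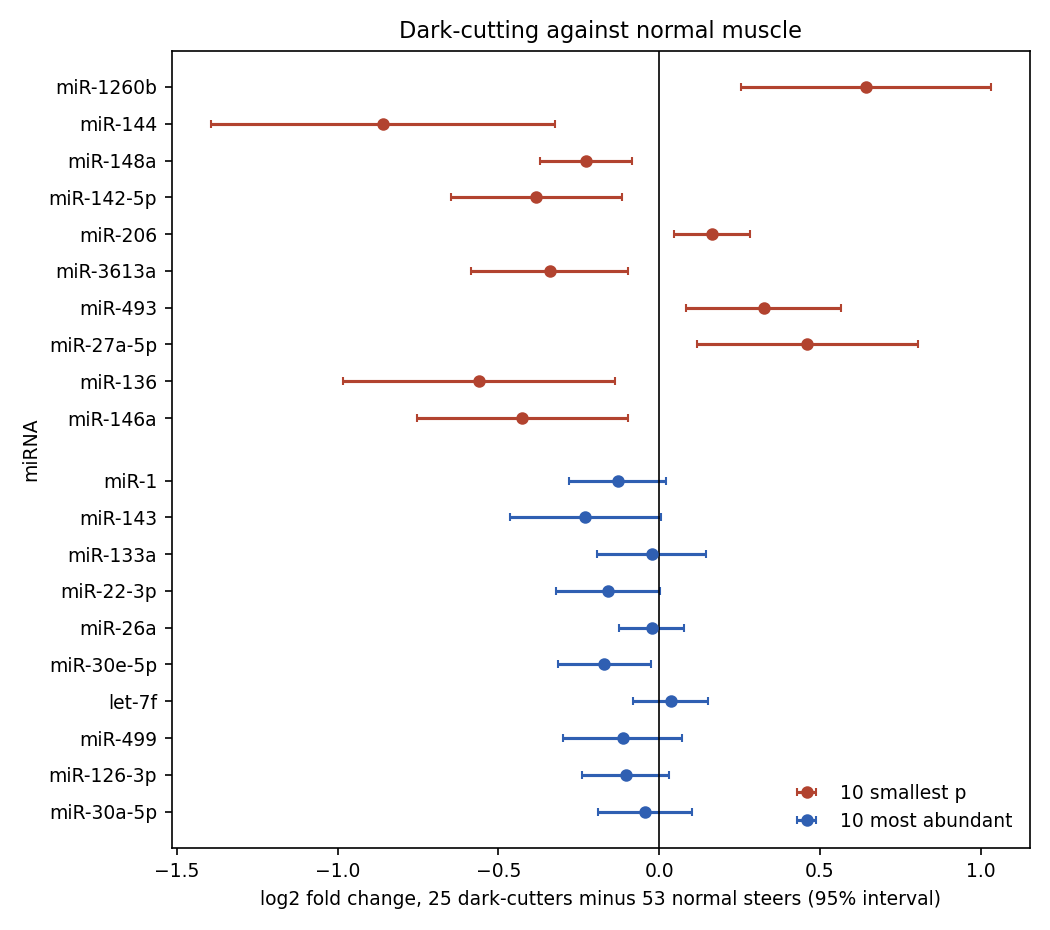
Log2 fold change of 25 dark-cutting against 53 normal steers (x axis) with its 95% interval (bars) for the 10 miRNAs with the smallest p and the 10 most abundant. The values reach from -0.86 for miR-144 to 0.64 for miR-1260b, and none passed the adjusted test.

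Among the miRNA lists, the glucose and lipid metabolism list holds miR-378 and its relatives with miR-103, miR-107 and miR-27. Of its 9 tested members 8 had a log2 fold change above 0 (median 0.11), such as miR-378 at 0.09 ± 0.06 (SE), miR-103 at 0.12 ± 0.06 and miR-378b at 0.21 ± 0.13. The largest was that of the rare miR-27a-5p (3.98 CPM), at 0.46 ± 0.17, while the abundant miR-27a-3p (863 CPM) was at -0.02 ± 0.10. Near-identical miRNAs such as miR-378 and its relatives can share reads, which was not checked by sequence. The 9 members need not be independent. The imprinted DLK1-DIO3 cluster, a large group of miRNAs read from the maternal chromosome, had 20 of 26 members above 0 (median 0.14). Examples were miR-493 at 0.33 and miR-543 at 0.34 ± 0.16, while miR-136 of the same cluster was at -0.56. The white blood cell list had 8 of 8 members below 0 (median -0.15), among them miR-223 at -0.25 ± 0.17 and miR-150 at -0.15 ± 0.11. Normal replicate 19 was also the highest of all steers in miR-142-5p (7.19 log2 CPM) and miR-223 (5.04 log2 CPM). With each of the 78 steers left out in turn, the largest adjusted p of this list was 0.0378 by camera with a preset correlation, while with all steers adjusted p = 0.402 with an estimated correlation.

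These 3 of 15 tested lists passed limma's camera test with a preset correlation of 0.01, with adjusted p = 0.00216 for glucose and lipid metabolism, 0.00216 for the DLK1-DIO3 cluster and 0.00834 for white blood cells. With a correlation estimated per list, adjusted p was 0.0585, 0.402 and 0.402, and no list passed. With fry in one direction, only glucose and lipid metabolism passed (adjusted p = 0.0235), and with fry in either direction no list did. Permuting the phenotype, which keeps the correlation between miRNAs, gave p = 0.0218, 0.0508 and 0.157 for the median log2 CPM difference of these 3 lists (adjusted p = 0.263, 0.263 and 0.350), and no list passed. Of the members of these 3 lists, none passed over all miRNAs. Adjusted over the list alone, miR-142-5p (p = 0.0427) and miR-146a (p = 0.0468) passed in the white blood cell list, and none did in the glucose and lipid metabolism list or the DLK1-DIO3 cluster. Both lay near the threshold: with single steers left out, miR-142-5p no longer passed for 29 and miR-146a for 38 of the 78 steers, normal replicate 19 among them (p = 0.0688 for each without it). Scaling by total count alone moved the median of the log2 fold changes by 0.11, and the counts above 0 then became 9 of 9, 22 of 26 and 1 of 8.

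The red blood cell list had 7 of 8 members below 0 (median -0.09, adjusted p = 0.165 by camera), but 6 of 8 with DESeq2's size factors and 4 of 8 with scaling by total count alone. Its members included miR-16a at -0.17 ± 0.08 and miR-486 at 0.08 ± 0.09, and adjusted over the list alone miR-144 passed (p = 0.0160), but not without normal replicate 19 (p = 0.117), where its log2 fold change went from -0.86 to -0.51. All 8 fibroblast members were below 0 (median -0.10, adjusted p = 0.133), with miR-21-5p at -0.06 and miR-29a at -0.10, but 4 of 8 were with total count scaling. In the myomiR list 4 of 6 members were below 0 (median -0.07, adjusted p = 0.827), the median being 0.04 with total count scaling. There miR-206 passed when adjusted over the list alone (p = 0.0399), but not with any of 21 of the 78 steers left out (p up to 0.122, without replicate 2 of degree 2/3). Both slow-fibre miRNAs were below 0, with miR-208b, encoded in an intron of MYH7, at -0.33 ± 0.17 and miR-499 at -0.11 ± 0.09 (adjusted p = 0.169).

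The muscle atrophy list had 5 of 8 members above 0 (adjusted p = 0.165), with miR-24-3p at -0.06 and miR-27b at 0.03, and the inflammation list had 5 of 6 below 0 (adjusted p = 0.338). With total count scaling these became 7 of 8 above 0 and 3 of 6 below 0. Endothelial miR-126-3p was at -0.10 and miR-126-5p at -0.05, and of the smooth muscle and pericyte pair miR-143 was at -0.23 and miR-145 at 0.07. The medians of these lists were -0.02 and -0.08, and 0.08 and 0.02 with total count scaling. In the let-7 family, 7 of 10 members were above 0 (median 0.03), with let-7f at 0.04 and let-7a-5p at 0.08. With total count scaling 9 of 10 were above 0, the median being 0.14 (adjusted p = 0.104 by camera). The miR-17-92 list held miR-92a at -0.0039 and miR-25 at -0.05, and its median was -0.0039 while camera pointed upward, the median being 0.00069 with DESeq2's size factors and 0.11 with total count scaling. The nerve list had miR-128 at -0.07 and miR-9-5p at 0.09, with a median of 0.01 while camera pointed downward. The liver list had miR-194 at 0.0067 and miR-192 at 0.04. With TMM scaling, adjusted p was 0.827 or more by camera for each of these lists from the endothelium onward, and no member passed when adjusted over the list alone. No miRNA of the skin epithelium or hypoxia lists passed the filter on low counts.

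**Figure D2:**
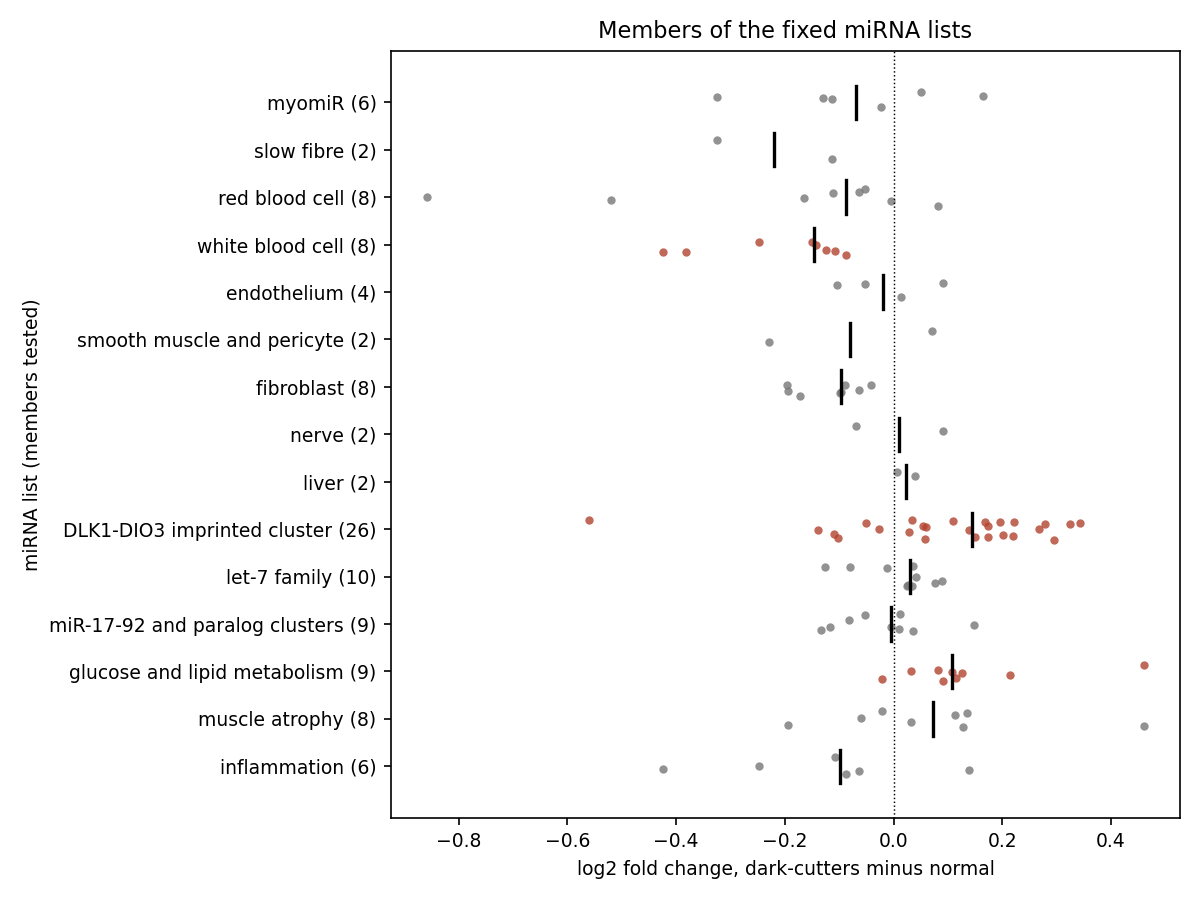
Log2 fold change of each tested member of 15 miRNA lists (points, x axis), dark-cutting against normal steers, with the list median (black bar) and the number of members in brackets. Lists in red (white blood cell, median -0.15; DLK1-DIO3, 0.14; glucose and lipid metabolism, 0.11) passed camera with a preset correlation, and no list passed with an estimated one or with the phenotype permuted.

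Steers of degree 2/3 had higher miR-1260b than normal steers, with a log2 fold change of 1.54 ± 0.34 (SE) or 2.90-fold. Log2 CPM was 3.36 ± 0.43 (SD, n = 4) against 1.77 ± 0.72 (SD, n = 53), and all 4 steers lay above the normal median. The reads named miR-1260b were not checked by sequence here, so an origin in other small RNAs such as tRNA fragments was not tested. This miRNA was of low abundance, with 32.0 counts per library on average against 10.5 in normal steers. It was the only one of 272 miRNAs to pass edgeR's test (adjusted p = 0.00629), with 7 at an unadjusted p under 0.05 (13.6 by chance). It was also the only call of DESeq2 and of limma-voom. The call was lost without replicate 1 (adjusted p = 0.0870) or without replicate 4 (adjusted p = 0.240), where log2 fold changes were 1.496 and 1.37. Next in rank, and not passing, were miR-340 at -0.55 ± 0.21, miR-2285av at -0.78 ± 0.31 and miR-206 at 0.29 ± 0.13 (adjusted p = 0.988 by edgeR).

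Against the same normal steers, degree 1/3 had miR-493 at 0.58 ± 0.17 (SE), miR-23a at 0.31 ± 0.11, miR-432 at 0.60 ± 0.23, miR-425-5p at -0.25 ± 0.09 and miR-143 at -0.47 ± 0.18. Degree 1/4 had miR-2422 at 0.72 ± 0.32, miR-21-5p at -0.19 ± 0.09 and miR-504 at -0.33 ± 0.15. Degree 1/2 had miR-11986b at -1.60 ± 0.50, miR-2285ba at -1.76 ± 0.68, miR-29b at -0.66 ± 0.27 and miR-655 at 0.81 ± 0.33. None of these passed edgeR's test, whose smallest adjusted p was 0.288 for 1/3, 0.998 for 1/4 and 0.569 for 1/2. DESeq2 and limma-voom also made 0 calls in each, and an unadjusted p under 0.05 was reached by 25, 3 and 13 of 272 miRNAs by edgeR, 25, 6 and 13 by DESeq2 and 32, 9 and 16 by limma-voom. Chance alone would give 13.6 of 272. In data simulated in the same way, with 48 changes at once, the share of 2-fold changes recovered was 90.6% for 1/3, 86.2% for 1/4, 63.1% for 1/2 and 71.9% for 2/3.

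Over all 78 steers, miR-1260b had a positive slope on the degree of dark-cutting, at 1.67 ± 0.40 (SE) log2 units per unit of degree (adjusted p = 0.0220 by edgeR). Normal steers were taken as 0, so such a slope can come from normal against dark-cutting steers alone. The single steer of degree 3/4 was at 2.18 log2 CPM, below the 2.88 to 3.76 of degree 2/3. The slope was positive for miR-206 (0.45 ± 0.13) and miR-2422 (1.61 ± 0.45) and negative for miR-148a (-0.57 ± 0.17), each with adjusted p = 0.0739. Below these came miR-3613a at -0.81 ± 0.28 and miR-142-5p at -0.83 ± 0.30. The call of miR-1260b was the only one of 272 tests, and DESeq2 called 3, adding miR-206 and miR-2422. An unadjusted p under 0.05 was reached by 30 (13.6 by chance), and 8 of 100 splits, the real one counted, had as many. For miR-1260b the call was not kept in every setting. Without the 4 steers of degree 2/3 its slope was 0.96 (adjusted p = 0.392), and with limma-voom adjusted p was 0.0510, the range over the alternatives being 0.00259 to 0.392.

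Within the 25 dark-cutting steers, the slope was -1.61 ± 0.47 (SE) for miR-340, 2.39 ± 0.91 for miR-1260b and 0.59 ± 0.25 for miR-206. The 8 steers of 1/2 or more differed from the 17 of 1/3 or less by -0.57 ± 0.16 in miR-340, -0.63 ± 0.24 in miR-885 and 0.45 ± 0.19 in miR-1343-3p. None of 251 miRNAs passed edgeR's test in either comparison, with smallest adjusted p of 0.392 and 0.277, nor with DESeq2 or limma-voom. An unadjusted p under 0.05 was reached by 9 and 6 by edgeR, 9 and 7 by DESeq2 and 10 and 8 by limma-voom, where chance alone would give 12.6. In simulated data with 48 changes at once, slopes of 2-fold per 1/2 unit of degree were recovered at 63.1%. For 2-fold differences between higher and lower degrees the share was 94.4%. In the 6 contrasts between the degrees 1/4, 1/3, 1/2 and 2/3 there were 0 calls, the smallest adjusted p being 0.311 for miR-1260b in 2/3 minus 1/4. So the excess of miR-1260b in degree 2/3 was not shown to differ from the other degrees.

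**Figure D3:**
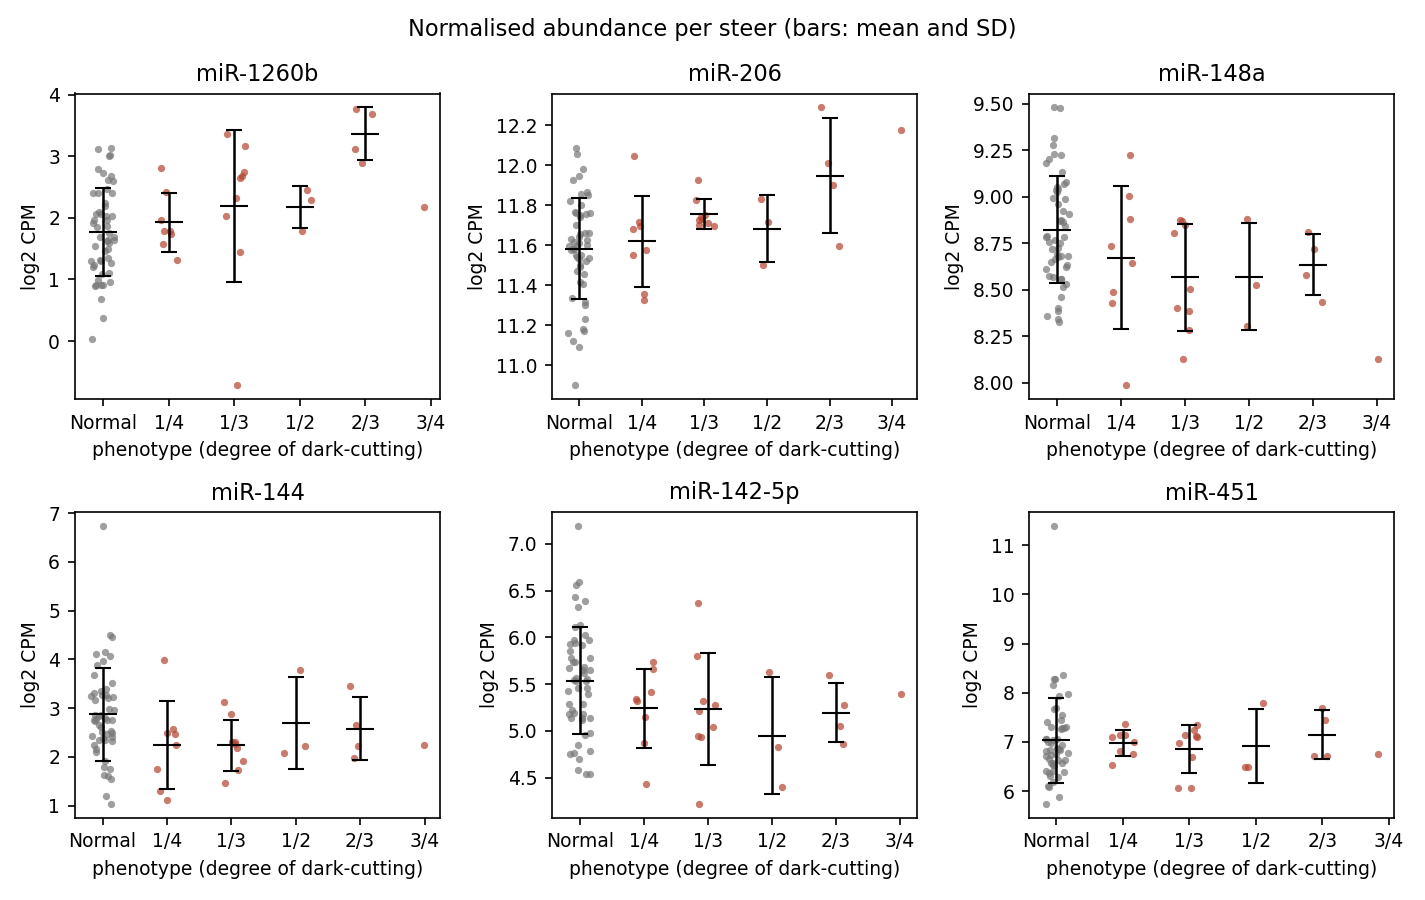
Normalised abundance (log2 CPM, y axis) of 6 miRNAs in each steer (points) by phenotype (x axis), with mean and SD (bars) where a group has more than 1 steer. The 4 steers of degree 2/3 lie between 2.88 and 3.76 for miR-1260b, and 1 normal steer stands apart in miR-451 at 11.39.

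The single steer of degree 3/4 has no replicate and was not tested as a group. Its miR-206 was 12.17 log2 CPM, 2.34 normal SD above the normal mean of 11.58, and 1 of the 53 normal steers was as far from that mean. Its miR-1260b was 2.18 log2 CPM, 0.570 SD above the normal mean. Of the 252 miRNAs, 13 lay more than 2 SD from the normal mean in this steer, against a median of 12 when each normal steer was left out and compared with the others.

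The authors' deposited table held the miRNAs with at least 10 counts over all libraries, tested with DESeq2 for dark-cutting against normal, and listed 0 at an adjusted p under 0.05 and 42 at an unadjusted p under 0.05. In the authors' deposited table the smallest adjusted p was 0.0541 for miR-2422 (log2 fold change 0.78 ± 0.20, SE), which was below the low-count filter used here for the comparison of the phenotypes. Of the 252 miRNAs in both, 247 had the same sign in the authors' deposited table as in the edgeR fit, and 21 had an unadjusted p under 0.05 in both. Of the authors' 42, 17 were not tested in the edgeR fit. Both are fits of the same contrast to the same counts, so their shared signs are no independent evidence.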

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

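The test of a graded rise below was chosen after the result was seen. Within the groups of degree 1/4, 1/3 and 2/3, single steers stood apart from the rest of their group in 17 of 240 sets of values, where chance, at about 1 in 20, gives 12. In degree 1/4 these were replicate 1 for miR-378 at 12.46 log2 CPM, replicate 2 for miR-655 at 4.68, replicate 5 for miR-628 at 2.65 and replicate 7 for miR-708 at 0.78. In degree 1/3 they were replicate 4 for miR-130a at 2.01, replicate 5 for miR-204 at 4.95, replicate 6 for miR-885 at 2.82 and miR-500 at 5.16, replicate 8 for miR-145 at 8.30, and replicate 9 for miR-302b at 1.91 and miR-1260b at -0.72. In degree 2/3 they were replicate 1 for miR-1434-5p at 2.96, replicate 2 for miR-16a at 9.58 and miR-2285av at 0.82, replicate 3 for miR-302b at 2.82, and replicate 4 for miR-21-5p at 11.51 and miR-1839 at 4.60.

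The steer of degree 1/3 at -0.72 log2 CPM had no count of miR-1260b, the miRNA called in degree 2/3, where log2 CPM was 2.88 to 3.76, and whose reads were not checked by sequence. A single steer carrying the excess over normal steers was tested by leaving out each of the 4. The log2 fold change stayed at 1.37 (SE 0.40) or higher, above the bound of 1 set for this test. All 4 steers also lay above the normal median. These values argue against 1 steer carrying the excess of miR-1260b in degree 2/3. A margin over that bound larger than the SE, an added demand, was not reached. The call itself did depend on single steers, being lost by edgeR without replicate 1 (adjusted p = 0.0870) or replicate 4 (adjusted p = 0.240). As many calls as the real 1 came up in 24 of 100 splits of the steers, the real grouping counted as 1 of them. Another split had up to 10 calls, so chance cannot be excluded. A graded rise may be a biological reading, but the slope within dark-cutting steers had an adjusted p of 0.998 by edgeR (unadjusted 0.0127), which decides neither way. The single steer of degree 3/4, at 2.18 log2 CPM, lay below the 4 steers of degree 2/3.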

How the results depend on the processing

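Covariates for animal number and for the main axis of normal libraries, left-out animals of the comparison of the phenotypes, the lists and their members, leaving out 3 libraries that stood apart (total under 2000000 counts, or miR-1 under 75%), the rows of the authors' table and the left-out degree 2/3 were chosen after seeing the data. Dark-cutting against normal kept 0 calls under every other setting and with each of the 78 steers left out, but had 2 without a low-count filter (miR-2284f and miR-2285cz), where more miRNAs of few counts were tested. The degrees 1/4, 1/3 and 1/2, the trend within dark-cutting steers and higher against lower degree kept 0 calls under all settings run. Degree 2/3 had 0 calls with the stricter filter, which removed miR-1260b, and 0 to 1 with single steers left out. The trend over all steers had 3 calls with DESeq2, with its size factors, with total count only (miR-1260b, miR-206 and miR-2422 in each), without a low-count filter (miR-2284f in place of miR-2422) and without the 3 libraries that stood apart, and 0 with the stricter filter, with limma-voom and without the 4 steers of degree 2/3. The cause was not tested except where the filter removed the miRNA. Of the lists, 0 passed with an estimated correlation, 1 with fry in one direction and 0 with fry mixed, and by camera with a preset correlation the 3 lists passed with every single steer left out. Without a low-count filter 3 lists also passed, but muscle atrophy took the place of the white blood cell list. At an unadjusted p, 21 miRNAs passed in both tables. Merging identical rows changed no count, and moved the log2 fold changes of dark-cutting against normal by 0 at the median. It leaves nearly identical rows such as miR-23b-3p and miR-10174-3p apart, so it does not test double counting among them.

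Of 569 values of single miRNAs under the alternatives, 21 changed sign, all of miRNAs near 0 that passed no test. The log2 fold change of miR-92a became 0.00089 with DESeq2, 0.00069 with its size factors, 0.11 with total count only, 0.012 without a filter, 0.0074 with the stricter filter, 0.00032 with the animal-number range, 0.022 without the 3 libraries and 0.0010 on the authors' rows. With total count only, which raised all values by 0.11 at the median, miR-133a became 0.0915, miR-126-5p 0.0569, miR-21-5p 0.0349, miR-29a 0.0103, miR-128 0.0697, miR-25 0.0676, miR-24-3p 0.0244, miR-26a 0.0823 and miR-30a-5p 0.0683. miR-194 became -0.0055 with limma-voom and -0.0082 with log10 total count as a covariate, miR-133a 0.0262 with the main axis as a covariate, and miR-26a 0.012 without the 3 libraries. Values also moved by over 1.5 times without a change of sign, and the following are examples. With the red blood cell list as a covariate, which holds miR-144 itself, miR-144 went from -0.86 to -0.19, miR-142-5p from -0.38 to -0.22 and miR-208b from -0.33 to -0.16. With the main axis as a covariate miR-144 was at -0.42 and miR-208b at -0.17. With total count only miR-148a went from -0.23 to -0.15 and miR-206 from 0.16 to 0.27. Depth limits miRNAs of few counts, such as miR-1260b.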

Other observations

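The tests of the animal-number range, of shared reads and of miR-208b, and the splits for the lists and for the trend within dark-cutting steers, were chosen after the results were seen, and so was the demand that the red blood cell test also hold without 1 steer. Across the 53 normal steers, slow-fibre miR-208b varied together with the white blood cell list. Pearson's r between miR-208b and the list mean was 0.682 (permutation p = 1e-05, the smallest the permutations can give) and Spearman's rho was 0.632 (permutation p = 1e-05). These p-values are for this 1 pair and take no account of its choice after the results were seen. Without the 2 steers farthest from the miR-208b median, r was 0.639, and within the steers numbered below 600 and the rest it was 0.627 and 0.681. Of 244 miRNAs outside the list, 3 had an r at least that high, both numbers counting miR-208b itself. The other slow-fibre miRNA, miR-499, had an r of 0.135. One shared axis of both among normal biopsies is a hypothesis, and no explanation for it was tested.

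Log2 fold changes of miR-144, miR-142-5p and miR-146a were below 0 in dark-cutting steers, and passed when adjusted over the red (miR-144) or white blood cell list alone but not over all miRNAs, nor did miR-146a over the inflammation list alone (p = 0.0702), and without normal replicate 19 none of the 3 passed (p = 0.117, 0.0688 and 0.0688). Less red blood cell RNA may account for part of this: the upper 95% bound of miR-451 was -0.0124, below 0, which met the bound set for this test in advance. Without normal replicate 19 the interval was -0.34 to 0.22, so that result rests on 1 steer and the explanation stays open. For less white blood cell RNA, the other 6 members of the list had a median difference of -0.11, inside the permuted range of -0.15 to 0.15, which leaves it open. Adding the animal-number range to the model did not put it to a test, since it moved all log2 fold changes by only 0.00171 at the median. Each of the 3 miRNAs kept at least 94.0% of its log2 fold change there. The range stays open: miR-144 was at -0.14 ± 0.35 below 600 and -1.11 ± 0.35 above (p = 0.0938 for the difference by edgeR, adjusted p = 0.852). Normal replicate 19 was numbered above 600, and the ranges were not compared without it.

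miR-23b-3p and miR-10174-3p had nearly the same count in each steer, with the smaller at least 99.0% of the larger. This is consistent with the same reads being counted in both rows, and values of such pairs are not independent. No biological explanation was tested.

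Whether the phenotypes differ in their whole profile was tested as a hypothesis. They accounted for 1.93% of the variance of log2 CPM over 252 miRNAs, against a median of 1.24% in 10000 permutations (permutation p = 0.0436). Lower and higher degrees, each set against a separate part of the normal steers, had log2 differences with a covariance of 0.0122 and a correlation of 0.347, and the covariance was above the 95th percentile of permuted phenotypes, 0.00815 (permutation p = 0.0160). A small shift shared by both ranges of degree is a hypothesis, while no single miRNA passed in the pooled comparison. The dark-cutting differences correlated with the main axis of normal libraries over miRNAs at 0.310 in size, between the median of 0.240 and the 95th percentile of 0.575 of permuted phenotypes, which does not decide whether that axis carries them.

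Other splits of the steers gave counts as large, so chance cannot be excluded for the counts of miRNAs or of lists. Each number of matching splits below is out of 100 and counts the real grouping as 1 of them. The real 23 miRNAs at an unadjusted p under 0.05 in dark-cutting against normal steers were matched in 14 of 100 splits, with up to 63 in another. For degree 1/4 the real 3 was matched in 99 of 100 (up to 46), for 1/3 the real 25 in 13 (up to 56), and for 1/2 the real 13 in 48 (up to 52). For higher against lower degree the real 6 was matched in 82 (up to 63), and for the trend within dark-cutting steers the real 9 in 58 (up to 36). The 1 call of the trend over all steers was matched in 19 (up to 12), and the 3 lists in 8 (up to 5). By its own camera p, the glucose and lipid metabolism list was matched in 2 of 100 splits (real p = 0.000262, smallest other 7.21e-05), white blood cells in 4 (0.00167, 2.76e-05) and the DLK1-DIO3 cluster in 11 (0.000288, 3.39e-27). These were picked as the called ones of 15 lists, and with the phenotype permuted the medians of none of them passed (adjusted p = 0.263, 0.350 and 0.263), so chance cannot be excluded for any of them. Splits with several times the real count point to a structure of the samples, or to miRNAs that vary together, and the cause was not tested.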
